A study of Mus musculus with 8 samples.

How the data were processed

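The material was epidermis of mouse skin, isolated with trypsin, from control and Ovol1/2 iDKO mice at 25 and 52 DPI, 2 biological replicates per group, 8 libraries in all. Per the labels' protocols RNA was extracted with Trizol and libraries were made with a Clontech SMART-seq v4 kit for low input. Per the submitters' processing notes FastQC 0.11.9, Trimmomatic 0.35, STAR 2.5.2a and DESeq2 1.24.0 were used with the builds GRCm38 and mm10. Their settings, the annotation release and the filters are not given in the sources used here. The values deposited are raw counts of reads per gene, 1 table per library, each with 54838 genes and 3 columns in the layout of STAR's gene counts, which are reads counted without regard to strand and reads on each strand. The tables hold no normalized values and no unassigned reads. Reads shared by near-identical genes could not be told apart from these tables.

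The column without regard to strand was used for all libraries. Although the labels give 1 kit, the replicate 2 libraries held 95.4% to 95.7% of the counts assigned by strand on the second strand and the replicate 1 libraries 49.8% to 49.97%. In the replicate 1 libraries reads of a gene and of an overlapping antisense gene cannot be told apart. The second-strand column for the replicate 2 libraries was tried as an alternative. Gene symbols were matched by identifier for 54723 of the genes, and 115 kept their identifier. Coordinates are those of GRCm38. The library totals were 9824307 to 50711381 counts. Samples were grouped by genotype and time as labelled.

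Genes were tested with edgeR 4.0.16 (R 4.3.3) on the deposited counts. Genes with low counts were removed with filterByExpr on the 4 groups, which left 17839 genes, 14101 of them protein coding, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 8 libraries, with 4 residual degrees of freedom, and gave the comparison of iDKO with control at 25 DPI and at 52 DPI, the difference between these effects, and 52 with 25 DPI in each genotype. A model with time and genotype, with 5 residual degrees of freedom, gave the comparison across both times. P values were adjusted by the Benjamini-Hochberg method over all tested genes, and an adjusted p under 0.05 was called. Values per library are CPM, counts scaled by library size and TMM, and log2 fold changes and their standard errors come from edgeR unless another tool is named. P values without a block measure the spread between the 2 replicates of each group. Replicates 1 and 2 also differed in the share of counts by strand, so this spread is not biological alone. With the block within time described below, p values measure how far the difference between iDKO and control varied between pairs.

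Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the 34 lists with at least 3 tested genes, and again with an estimated correlation and with fry. With an estimated correlation and with fry 0 lists were called in any comparison. The lists covered basal keratinocytes, spinous and granular keratinocytes, the cornified envelope, barrier lipids, activated keratinocytes, antimicrobial genes, cytokines and chemokines, the type I interferon response, antigen presentation and mesenchymal transition. Others covered epithelial junctions, the actin cytoskeleton, the cell cycle, p53 and DNA damage, hair follicle stem cells and outer root sheath, hair shaft and inner root sheath, sebaceous glands, melanocytes, Langerhans cells, macrophages, T cells and the type 17 response. The remaining lists covered dermal fibroblasts, endothelium, adipocytes, skeletal muscle, erythroid cells, immediate-early and dissociation stress genes, glycolysis and hypoxia, cholesterol synthesis, NRF2 and oxidative stress, circadian genes, the mitochondrial genome and sex-linked genes. Of 36 lists fixed, those of the targets and of neutrophils had fewer than 3 tested genes.

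The tests, lists, alternatives and the rule for naming genes were chosen before the data were examined, except where stated. The rule named the targeted and sex-linked genes, called genes ranked by fold change, and up to 4 members of each list with the smallest unadjusted p in each genotype comparison. As edgeR called 0 genes, genes ranked by p across both times under the replicate block within time, up to 10 per direction with a mean log2 CPM of at least 1 and the same direction in all 4 pairs, were added after the data were examined, and so were genes called by DESeq2. The list tests of the difference between times and across both times were added then as well.

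The labels number the replicates 1 and 2 in every group. The deviations of the replicate 1 and 2 libraries from their group mean correlated between groups at 0.395 to 0.793 over the 17839 genes, in all 6 pairs of groups, so the numbers were taken to pair the libraries. Fits with the replicate number as a block, and with the number within each time as a block (4 pairs, 2 residual degrees of freedom), were run beside the model without a block, and their values are given where they change a call of a list or of a gene named in the report.

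Alternatives chosen in advance were RLE scaling and library size alone, DESeq2 1.42.0, limma-voom, no filter and a stricter filter of 2 CPM in 2 libraries, a minimum absolute log2 fold change of 1, removal of mitochondrial genes, both blocks, the 4 libraries of 1 time alone and no time term. Each library was also left out in turn, which leaves 1 library in a group that is assumed to vary like the others. DESeq2 and limma-voom with a block, DESeq2 without single libraries or pairs, the second-strand column and the omission of control 25 DPI replicate 1 together with iDKO 52 DPI replicate 2 were added after the data were examined.

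The procedure was tested on simulated data, with counts drawn for the 17839 genes and 200 genes changed. The draws used the real library sizes, each gene's mean per replicate number over both times and genotypes, and the spread within pairs. They lack the deviations of single libraries and match the models with a block, which may flatter the recovery of those models. For iDKO against control at 25 DPI edgeR without a block recovered 0% of genes at every fold, and with the block within time 11.9%, 82.1% and 98.5% of those changed 2-, 4- and 16-fold, with 10 false among 138 calls. At 52 DPI it recovered 0%, and with the block 17.9%, 74.6% and 100% with 19 false among 167 calls. Across both times the model without a block recovered 1.49%, 25.4% and 77.3% with 0 false among 69 calls, and with the block within time 50.75%, 100% and 100% with 12 false among 186. The same comparison by DESeq2 with the block within time recovered 74.6%, 100% and 100% with 36 false among 225 calls, more than its threshold of 0.05 allows. The false calls by edgeR with the block also exceeded that share in each comparison. A T cell list raised 4-fold at 52 DPI was called by camera with the preset correlation (adjusted p = 9.94e-56). It was missed with an estimated one (adjusted p = 0.11). With the preset correlation 2 lists were called there, although the T cell list was the only list raised. In the real libraries the estimated correlation at 52 DPI was 0.54 for the T cell list and -0.267 to 0.819 over the lists tested. As the draws lack the deviations of single libraries, the simulation cannot check the preset correlation, on which the list calls rest. Results for certain single genes are not reported here. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).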

Results

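RNA was sequenced from mouse skin epidermis, the outer epithelium of the skin, which the labels describe as isolated with trypsin. The 8 libraries formed 4 groups of 2 biological replicates, control and Ovol1/2 iDKO mice at 25 DPI and at 52 DPI, with iDKO and DPI written as the labels give them. Ovol1 and Ovol2 encode zinc finger transcription factors of epithelia, and the series is concerned with epithelial plasticity, the skin barrier and inflammation. The control libraries held 16964289 and 50711381 counts at 25 DPI and 24732179 and 13024905 at 52 DPI. The iDKO libraries held 9824307 and 28783756 counts at 25 DPI and 27874977 and 14402046 at 52 DPI. Of the genes in the count tables, 17839 had enough counts to be tested.

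The libraries differed more by replicate number than by genotype or time. In the replicate 2 libraries 95.4% to 95.7% of the counts assigned by strand lay on one strand, and in the replicate 1 libraries 49.8% to 49.97%. The first principal component, with 56.5% of the variance, placed the 4 replicate 1 libraries on one side and the 4 replicate 2 libraries on the other. Log2 CPM correlated at 0.796 to 0.936 between the 2 libraries of a group and at 0.946 to 0.986 between the iDKO and control libraries of the same time and replicate number. Each iDKO library is therefore also set beside the control library of its time and number, which gives 4 pairs. Transcripts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in all 4 libraries at 25 DPI and had 0 counts in all 4 at 52 DPI. Xist, the transcript of the inactive X chromosome, was at 0.119 to 0.342 CPM at 25 DPI and at 131 to 1139 CPM at 52 DPI. Sex and time thus changed together.

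**Figure D1:**
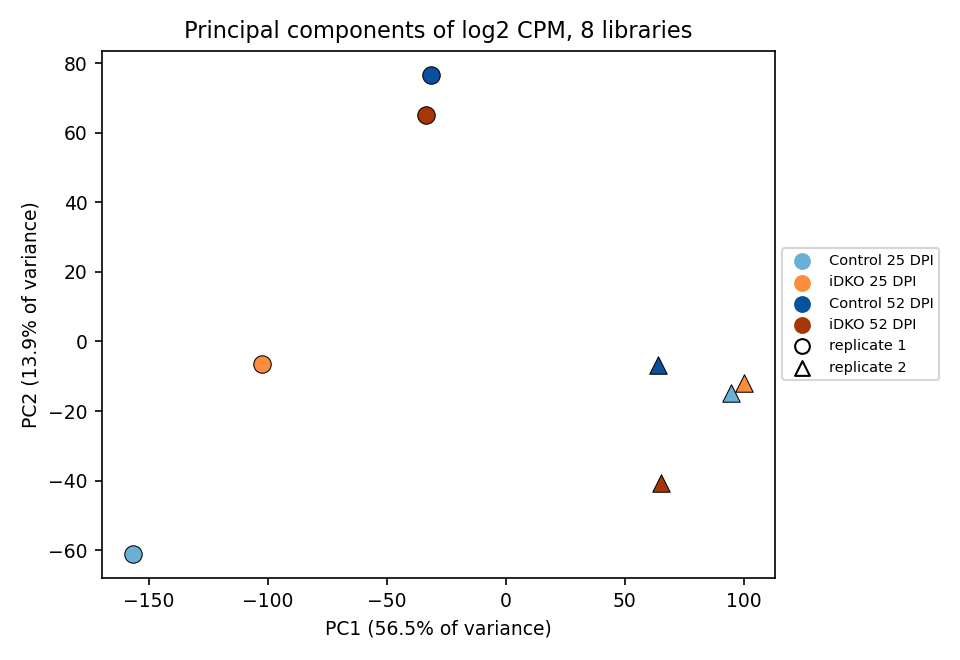
Scores of the 8 libraries on the first 2 principal components of log2 CPM (axes in score units, with 56.5% and 13.9% of the variance), colored by group, with circles for replicate 1 and triangles for replicate 2. The circles lie at negative and the triangles at positive scores on the first component.

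The counts of the targeted genes were higher, not lower, in the iDKO library of all 4 pairs, by small ratios in some. Ovol1 (ENSMUSG00000024922, GRCm38 chromosome 19, 5549136 to 5560646, minus strand) was at 134.9 and 36.3 CPM in the control libraries at 25 DPI and at 148.1 and 204 CPM in the libraries labelled iDKO. At 52 DPI it was at 62.7 and 157.2 CPM in control and at 99.0 and 193.5 CPM in the libraries labelled iDKO. Ovol2 (ENSMUSG00000037279, GRCm38 chromosome 2, 144305175 to 144332146, minus strand) was at 24.9 and 11.6 CPM in control and 44.6 and 16.7 CPM in the libraries labelled iDKO at 25 DPI. At 52 DPI its values were 21.3 and 7.52 CPM in control and 22.3 and 9.16 CPM in the libraries labelled iDKO. Ovol1 had a log2 fold change of 1.04 (SE 0.78) at 25 DPI and 0.41 (SE 0.77) at 52 DPI, and Ovol2 of 0.75 (SE 0.79) and 0.12 (SE 0.79), none of them called by edgeR's quasi-likelihood test (adjusted p = 1.00 for each). The 25 DPI value of Ovol1 was 0.38 without control replicate 2 and 2.26 without control replicate 1. With the replicate block within time the values at 25 DPI were 1.31 (SE 0.54) and 0.68 (SE 0.24), also uncalled by edgeR (adjusted p = 0.731 for both). The sources used here do not say which part of either gene was modified, and a count over the whole gene does not show the loss of single exons. The labels are therefore unchecked by these 2 genes, and every direction given here is that of the libraries labelled iDKO.

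Zeb1, a transcription factor that represses epithelial genes, and Fkbp14, a prolyl isomerase of the endoplasmic reticulum, were the 2 genes called by DESeq2 at 25 DPI. The comparison asks how the epidermal transcriptome of the libraries labelled iDKO differed from control. Zeb1 was at 24.9 ± 14.8 CPM (SD, n = 2) in the libraries labelled iDKO and at 3.19 ± 0.209 CPM (SD, n = 2) in control, with a log2 fold change of 2.97 (SE 0.59). DESeq2 gave Zeb1 an adjusted p of 0.0296 and Fkbp14 (log2 fold change 4.02, SE 0.75) one of 0.0014, and edgeR called neither. With 1 library left out at a time DESeq2 kept Zeb1 only without control 25 DPI replicate 2 (adjusted p = 0.0492), and Fkbp14 only without control replicate 1 or 2 of this time (0.0256 and 0.00605). The adjusted p of Zeb1 by DESeq2 was 0.137, 0.104 and 1.00 without control replicate 1 and iDKO replicates 1 and 2 of this time, and 0.67 to 0.959 without a 52 DPI library. That of Fkbp14 was 0.41 and 0.742 without iDKO replicates 1 and 2 of this time and 0.0872 to 0.168 without a 52 DPI library. The log2 fold change of Zeb1 by edgeR lay between 2.175 and 3.51 without 1 library, and DESeq2 with the replicate block within time gave it an adjusted p of 7.38e-07. The count of genes by DESeq2 lay between 0 and 102 (102 without control replicate 2, 8 without control replicate 1). Sesn2, a stress-induced gene of the p53 response, was at 139.9 ± 120 against 40.6 ± 20.2 CPM (SD, n = 2 each). Il6, which encodes an inflammatory cytokine, was at 7.17 ± 1.31 against 1.87 ± 0.593 CPM (SD, n = 2 each), and neither tool called these 2 genes without a block. DESeq2 with the replicate block within time called Sesn2 (log2 fold change 1.55, SE 0.33, adjusted p = 0.00128), whose log2 fold change by edgeR was 0.46 without iDKO replicate 2. Krt16, a keratin of activated keratinocytes, had a log2 fold change of 1.22 (SE 0.57), and Irf1, a transcription factor of the interferon response, one of 1.51 (SE 0.68), also uncalled. The alarmin gene S100a9 had a log2 fold change of 3.29 (SE 1.31) from levels of 0.622 and 0.0496 CPM. Without iDKO replicate 2 the log2 fold changes of Krt16, Irf1 and S100a9 were 0.80, 0.90 and 1.82. With all libraries the lists that hold Krt16, Irf1, S100a9 and Il6 were not called at 25 DPI. The antimicrobial list had 3 members higher and 8 lower (median -0.45, adjusted p = 0.242 by camera). The antigen presentation list had 10 higher and 13 lower (-0.12, 0.833), and activated keratinocytes 7 and 7 (-0.28, 0.454). The cytokine and chemokine list, which holds Il6, had 15 higher and 11 lower (0.28, 0.253). The type I interferon list, which holds none of the named genes, had 11 higher and 13 lower (-0.04, 0.833). Without control replicate 1 the antigen presentation, activated keratinocyte and cytokine lists were called as higher. Without control replicate 2 the antigen presentation and antimicrobial lists were called as lower. Over all genes edgeR called 0 at an adjusted p under 0.05, with 75 genes at an unadjusted p under 0.05 against 892 expected by chance. It also called 0 with the replicate block within time, with 1162 at an unadjusted p under 0.05, of which 867 were higher and 295 lower. DESeq2 called 2 genes, both higher, and limma-voom called 0. In simulated counts, drawn with the spread within pairs, edgeR without a block recovered 0% of the genes changed 16-fold at this time. Its count of 0 without a block thus does not exclude changes of that size. With the block within time, which matches how the counts were drawn, edgeR recovered 82.1% and 98.5% of those changed 4- and 16-fold.

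Genes of mesenchymal cells, of the dermis and of the barrier were higher as groups at 25 DPI. The mesenchymal transition list rose, with 15 of 21 members higher and a median log2 fold change of 0.51 (camera with the preset correlation, adjusted p = 0.00111). The call was lost with an estimated correlation (adjusted p = 0.48 with an estimated correlation). Besides Zeb1 its members included Mmp9, a matrix-degrading protease (log2 fold change 1.21, SE 0.50), Itga5, a fibronectin receptor subunit (1.55, SE 0.75), and Tgfb1, a growth factor (0.88, SE 0.53). Adjusted over the list alone edgeR called 1 of the 21 genes, Zeb1, against 0 adjusted over all genes tested, and 7 with the replicate block within time. The dermal fibroblast list rose with 14 of 16 members higher and a median of 1.10 (adjusted p = 0.00023 by camera, adjusted p = 0.663 with an estimated correlation). Its collagen genes Col1a1 and Col1a2 were at 28.7 ± 37.8 and 28.2 ± 31.7 CPM against 7.596 ± 9.73 and 9.19 ± 9.02 CPM (SD, n = 2 each). The barrier lipid list rose with 18 of 25 members higher and a median of 0.25 (adjusted p = 0.00424 by camera, adjusted p = 0.365 with an estimated correlation). Alox12b, a lipoxygenase of the lipid barrier, and Sdr9c7, a dehydrogenase of the same pathway, had log2 fold changes of 2.78 (SE 1.05) and 2.38 (SE 1.20). The cornified envelope list rose by the test with 15 of 27 members higher and a median of only 0.06 (adjusted p = 0.0291 by camera, adjusted p = 0.837 with an estimated correlation). Corneodesmosin (Cdsn) had a log2 fold change of 1.49 (SE 0.67) and loricrin (Lor) one of 1.54 (SE 0.87). Without the iDKO replicate 2 library the adjusted p was 0.257 for the mesenchymal, 0.463 for the fibroblast, 0.112 for the barrier lipid and 0.311 for the cornified envelope list, and Col1a1 and Col1a2 had log2 fold changes of -1.94 and -0.63. The fibroblast and cornified envelope lists then pointed down, and Cdsn, Lor, Alox12b and Sdr9c7 had log2 fold changes of 0.21, 1.04, 1.28 and 1.07. By DESeq2 with the replicate block within time Itga5 and Col1a2 were called (adjusted p = 0.00519 and 0.0312). Without control replicate 1 it was 0.327 for the mesenchymal and 0.283 for the fibroblast list, with log2 fold changes of 0.86 for Itga5 and 0.43 for Tgfb1, and without iDKO replicate 1 it was 0.0727 for the barrier lipid list. Without control replicate 2 it was 0.629 for the barrier lipid and 0.942 for the cornified envelope list.

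Markers of T cells and melanocytes were lower at 25 DPI. The T cell list fell, with 23 of 24 members lower and a median log2 fold change of -1.62 (camera, adjusted p = 1.67e-15), and the call was lost with an estimated correlation (adjusted p = 0.562 with an estimated correlation). Cd8a, a co-receptor of cytotoxic T cells, was at 3.21 ± 0.789 CPM against 29.7 ± 35.8 in control, and Klrk1, an activating receptor, at 7.62 ± 1.64 against 29.3 ± 26.7 (SD, n = 2 each). The melanocyte list fell with 9 of 10 members lower and a median of -1.60 (adjusted p = 1.32e-05 by camera, adjusted p = 0.608 with an estimated correlation). Its pigment genes Dct, Tyrp1 and Pmel had log2 fold changes of -2.37 (SE 1.02), -2.41 (SE 0.93) and -1.53 (SE 0.73). The erythroid list fell with 5 of 5 members lower and a median of -4.96 (adjusted p = 0.000206 by camera, adjusted p = 0.608 with an estimated correlation). Control replicate 1 stood apart in these lists, with Cd8a at 55.0 CPM against 4.41 in control replicate 2, Dct at 217.2 against 16.1 and the globin gene Hbb-bs at 47.1 against 0.357. Without that library the adjusted p was 0.714 for the T cell, 0.371 for the melanocyte and 0.261 for the erythroid list, and all 3 lists pointed up. Without it the log2 fold changes of Cd8a, Klrk1, Tyrp1, Dct, Pmel, Trac and Cxcr6 were -0.49, -0.48, -0.16, 0.46, 0.01, 0.25 and 0.54. Without iDKO replicate 1 it was 0.057 for the melanocyte and 0.112 for the erythroid list, and with the replicate block within time 0.116 for the erythroid list.

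The remaining lists called at 25 DPI hold genes of hair and muscle. The list of hair shaft and inner root sheath genes fell with 12 of 17 members lower and a median of -0.47 (camera, adjusted p = 0.00347, adjusted p = 0.856 with an estimated correlation). The hair keratin Krt31 was at 0.311 ± 0.279 CPM against 1.91 ± 0.537 (SD, n = 2 each), with log2 fold changes of -4.00 to -1.855 without 1 library. The skeletal muscle list fell with 5 of 6 members lower and a median of -1.21 (camera, adjusted p = 0.00136, adjusted p = 0.365 with an estimated correlation). The muscle actin Acta1 was at 0.772 ± 0.447 CPM against 2.999 ± 0.844 (SD, n = 2 each). The hair list had an adjusted p of 0.469 without control replicate 1, where it pointed up, 0.686 without iDKO replicate 2 and 0.0536 without a filter on low counts, and the muscle list one of 0.426 without control replicate 2 and 0.2005 without iDKO replicate 1. With the replicate block within time the basal keratinocyte list was called in addition, as higher (median 0.13, adjusted p = 0.0151 against 0.139 without the block by camera), and not with an estimated correlation (adjusted p = 0.839 with the block and an estimated correlation). Its pair medians disagreed, at 1.22 and -0.10, and without a block it was called as lower without control replicate 1 (adjusted p = 0.00649) and as higher without control replicate 2 (4.42e-05). Krt14, a keratin of the basal layer, had a log2 fold change of 0.71 (SE 0.84, and 0.32 to 1.03 without 1 library). Over 34 tested lists 9 were called, and without control replicate 1 the calls were mostly of other lists. The mesenchymal, fibroblast, T cell, melanocyte, erythroid and hair shaft lists then lost their call. Activated keratinocytes, cytokines, antigen presentation, hair follicle stem cells, sebaceous, Langerhans cell, cholesterol synthesis and mitochondrial genes were called instead as higher. Basal keratinocyte, glycolysis and circadian genes were called as lower.

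At 52 DPI Zeb1 was the 1 gene called by DESeq2, at 18.8 ± 2.49 CPM (SD, n = 2) in the libraries labelled iDKO and 2.06 ± 0.0272 CPM (SD, n = 2) in control. Its log2 fold change was 3.19 (SE 0.60, DESeq2 adjusted p = 0.0175, edgeR adjusted p = 1.00). Vim, which encodes the intermediate filament of mesenchymal cells, was at 255.2 ± 134 against 71.0 ± 25.0 CPM (DESeq2 with the replicate block within time, adjusted p = 0.0173), and Mmp9 at 17.6 ± 1.92 against 9.21 ± 0.609 CPM (SD, n = 2 each). The kallikrein proteases of desquamation Klk7 and Klk5 were at 263 ± 241 and 22.2 ± 12.9 CPM against 24.8 ± 3.02 and 6.24 ± 0.487 CPM. Ccl22, a chemokine that attracts T cells, was at 41.2 ± 4.01 against 7.43 ± 1.86 CPM (SD, n = 2 each), and Il17a, the signature cytokine of type 17 T cells, at 1.78 ± 1.18 against 0.13 ± 0.183 CPM, with log2 fold changes of 2.67 to 8.36 without 1 library. Il17a was near the floor in control and was called by neither edgeR nor DESeq2, with or without the block within time. The type 17 list was not called at this time. Pnpla1, a lipid-processing enzyme of the barrier, had a log2 fold change of 1.29 (SE 0.56). The mesenchymal transition list, with 12 of 21 members higher and a median of 0.13, was not called (camera, adjusted p = 0.3), and adjusted over the list alone edgeR called 1 of its genes, Zeb1, and 2 with the replicate block within time. Over all genes edgeR called 0, with 143 at an unadjusted p under 0.05 against 892 expected by chance, DESeq2 called 1, Zeb1, and limma-voom called 0. EdgeR with the replicate block within time called 0, with 764 at an unadjusted p under 0.05. With 1 library left out DESeq2 called 0 to 20 genes (20 without iDKO replicate 1). Zeb1 had an adjusted p by DESeq2 of 1.00 without control replicate 1, control replicate 2 or iDKO replicate 2, 0.231 without iDKO replicate 1 and 0.0556 without iDKO 25 DPI replicate 2. Its log2 fold change by edgeR lay between 3.05 and 3.32 without 1 library, and DESeq2 with the replicate block within time gave it an adjusted p of 1.45e-07. Without iDKO replicate 2 the log2 fold changes of Vim, Klk7, Klk5 and Pnpla1 were 1.18, 1.90, 1.07 and 0.47. In the simulation edgeR without a block recovered 0% of genes changed 16-fold at this time, and with the block within time 74.6% and 100% of those changed 4- and 16-fold.

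**Figure D2:**
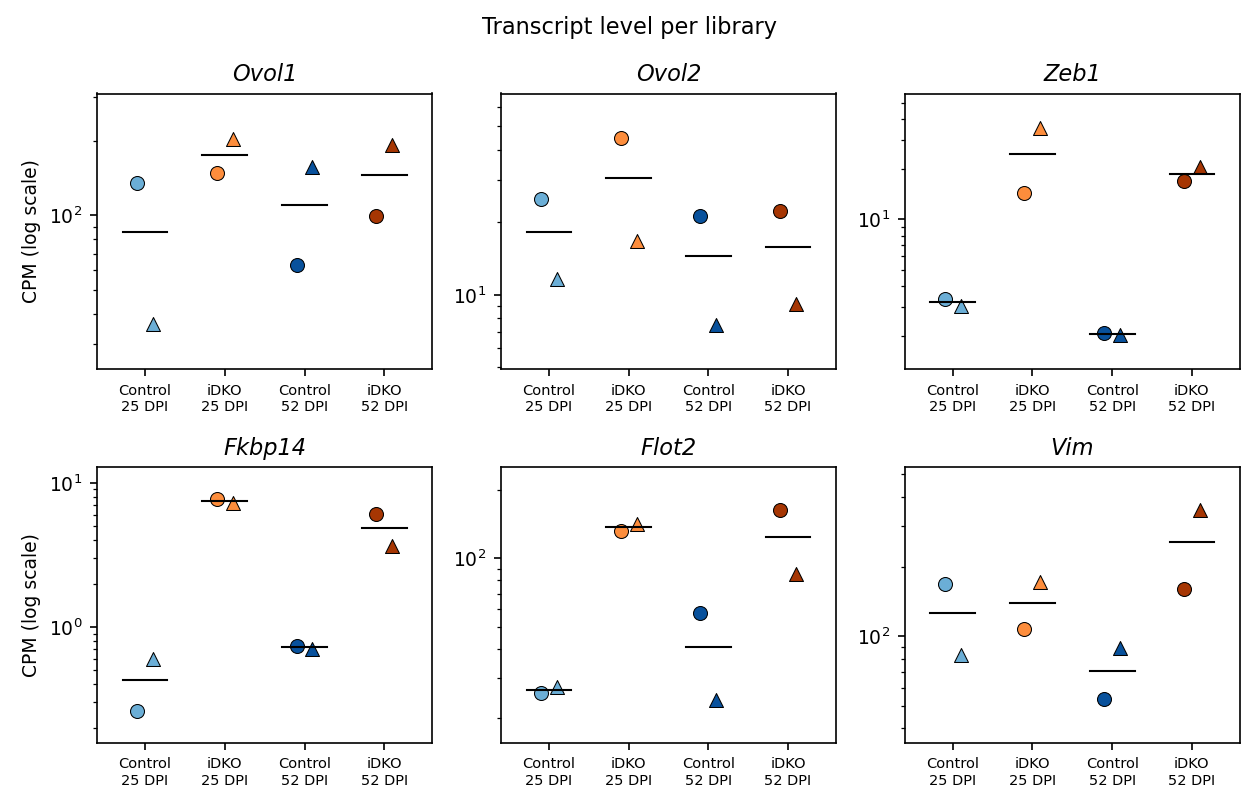
CPM (log scale) of 6 genes in each library, by group, with circles for replicate 1, triangles for replicate 2 and a line at the mean of the 2 libraries. All 4 libraries labelled iDKO lie above all 4 control libraries for Zeb1, Fkbp14 and Flot2, and not for Ovol1, Ovol2 and Vim.

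T cell genes were higher in the libraries labelled iDKO at 52 DPI. The list rose with 24 of 24 members higher, each in both pairs, and a median log2 fold change of 1.18 (camera, adjusted p = 4.99e-20, adjusted p = 0.363 with an estimated correlation). The granzyme gene Gzmc was at 15.1 ± 11.9 against 3.11 ± 1.74 CPM, Cd247, a chain of the T cell receptor complex, at 39.5 ± 21.9 against 14.1 ± 6.70 CPM (SD, n = 2 each). The inhibitory receptor gene Ctla4 was at 3.38 ± 2.43 against 0.358 ± 0.174 CPM (SD, n = 2 each). Il2rb, a receptor chain for interleukin 2 and 15, had a log2 fold change of 1.28 (SE 0.65). The macrophage list rose with 9 of 9 members higher and a median of 1.01 (camera, adjusted p = 0.00014, adjusted p = 0.363 with an estimated correlation), led by the scavenger receptor Cd163 (log2 fold change 3.46, SE 1.67, and 0.87 without iDKO replicate 2). These 2 lists kept their call and direction without each of the 8 libraries in turn, with a highest adjusted p of 0.000626 for T cells and 0.0394 for macrophages. Omitting a 25 DPI library leaves the 52 DPI groups whole, and the T cell median was then 1.175 to 1.199. Only the omissions at 52 DPI thus bear on single libraries. The T cell rise was larger in the pair of replicate 2, with pair medians of 0.34 and 2.40. The median of the list was 0.82 without iDKO replicate 2 and 0.77 without control replicate 2, against 1.18 with all libraries. Without iDKO replicate 2 the log2 fold changes of Gzmc, Cd247, Ctla4 and Il2rb were 1.08, 0.77, 2.17 and 0.67, against 2.26, 1.49, 3.18 and 1.28 with it. The Langerhans cell list rose with 11 of 12 members higher and a median of 0.82 (camera, adjusted p = 4.53e-05, adjusted p = 0.363 with an estimated correlation). Its member Mfge8, which encodes a phagocytic bridging protein, was at 180.5 ± 36.6 against 83.2 ± 5.06 CPM and the protease Ctss at 17.7 ± 0.105 against 6.76 ± 0.92 CPM (SD, n = 2 each). Without iDKO replicate 1 the adjusted p of the Langerhans cell list was 0.0719.

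Interferon, antigen presentation and antimicrobial genes were also higher at 52 DPI. The type I interferon list rose with 20 of 24 members higher and a median of 0.62 (camera, adjusted p = 5.48e-05, adjusted p = 0.552 with an estimated correlation). The nucleic acid sensors Zbp1 and Ddx58 had log2 fold changes of 2.03 (SE 0.90) and 0.88 (SE 0.48), that of Zbp1 being 0.76 without iDKO replicate 1 and 2.92 without control replicate 1. The antigen presentation list rose with 18 of 23 members higher and a median of 0.45 (adjusted p = 0.00313 by camera, adjusted p = 0.656 with an estimated correlation). H2-DMa, which loads peptides on class II molecules, had a log2 fold change of 1.15 (SE 0.77). The antimicrobial list rose with 10 of 11 members higher and a median of 0.93 (adjusted p = 4.53e-05 by camera, adjusted p = 0.363 with an estimated correlation). Chil1, a chitinase-like protein gene, was at 30.3 ± 14.1 against 4.15 ± 0.000898 CPM (DESeq2 with the replicate block within time, adjusted p = 0.0345) and S100a9 at 2.64 ± 1.33 against 0.439 ± 0.0441 CPM (SD, n = 2 each). The adjusted p of the interferon list was 0.329 without control replicate 2 and 0.666 without iDKO replicate 1, and that of the antigen presentation list 0.5765 and 0.542 without the same libraries. Without iDKO replicate 1 both lists pointed down. The antimicrobial list had an adjusted p of 0.13 without control replicate 1.

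The basal keratinocyte list was lower and the list of hair shaft and inner root sheath genes higher at 52 DPI, the latter through iDKO replicate 2. The basal keratinocyte list fell with 16 of 16 members lower and a median of -0.81 (camera, adjusted p = 1.55e-05, adjusted p = 0.489 with an estimated correlation). The basement membrane gene Lamb3 and the integrin Itgb1 had log2 fold changes of -0.86 (SE 0.98) and -0.59 (SE 0.64). The hair shaft and inner root sheath list rose with 14 of 17 members higher and a median of 1.66 (camera, adjusted p = 2.31e-09, adjusted p = 0.363 with an estimated correlation). Its keratins Krt71, Krt35 and Krt25 were at 81.3, 71.9 and 59.4 CPM in iDKO replicate 2 and at 0.879, 0.0314 and 0.0314 CPM in iDKO replicate 1, and the gap junction gene Gjb2 at 288 and 4.77 CPM. Without iDKO replicate 2 the adjusted p was 0.0998 for the basal and 0.913 for the hair list, which then pointed down, and the log2 fold changes of Krt71, Krt35, Krt25 and Gjb2 were 0.67, -1.55, -3.53 and -0.51. Those of Lamb3 and Itgb1 were then -0.31 and -0.26. The immediate-early and dissociation stress list fell with 14 of 18 members lower and a median of -0.38 (camera, adjusted p = 0.0113, adjusted p = 0.363 with an estimated correlation), including the nuclear receptor Nr4a1 (-0.86, SE 1.10). Its adjusted p was 0.311 without control replicate 2 (log2 fold change of Nr4a1 -0.28), 0.0719 without iDKO replicate 1 and 0.153 without iDKO replicate 2. With the replicate block within time the p53 and DNA damage list was called as lower (median -0.14, adjusted p = 0.0134 against 0.066 without the block by camera), and not with an estimated correlation (adjusted p = 0.704 with the block and an estimated correlation).

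Cholesterol synthesis and sebaceous genes were higher at 52 DPI, and red cell transcripts were higher in 1 of the 2 pairs. The cholesterol synthesis list rose with 18 of 20 members higher and a median of 0.28 (camera, adjusted p = 0.0327, adjusted p = 0.746 with an estimated correlation). The sebaceous list rose with 15 of 18 members higher and a median of 0.46 (camera, adjusted p = 0.0262, adjusted p = 0.746 with an estimated correlation). The sterol acyltransferase Soat1 had a log2 fold change of 1.26 (SE 0.62). The barrier lipid list was not called (median 0.18, adjusted p = 0.0941 by camera). The erythroid list had 5 of 5 members higher and a median of 2.27 (camera, adjusted p = 0.02, adjusted p = 0.656 with an estimated correlation), with pair medians of -0.52 and 3.12. The adjusted p was 0.912 for the cholesterol and 0.893 for the sebaceous list without control replicate 1, 0.212 for the cholesterol list without iDKO replicate 2, where it pointed down, and 0.775 for the sebaceous list without iDKO replicate 1. For the erythroid list it was 0.277 without control replicate 2 and 0.064 without iDKO replicate 2, where the list pointed down. It was called as lower without control 25 DPI replicate 1 and iDKO 52 DPI replicate 2 together (adjusted p = 0.0456). With the replicate number as a block the adjusted p was 0.0654 for the cholesterol, 0.161 for the sebaceous and 0.161 for the erythroid list. It was 0.326 for the erythroid list with the block within time, and without a filter on low counts 0.064 for the cholesterol and sebaceous lists. Over 34 lists 12 were called at 52 DPI.

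**Figure D3:**
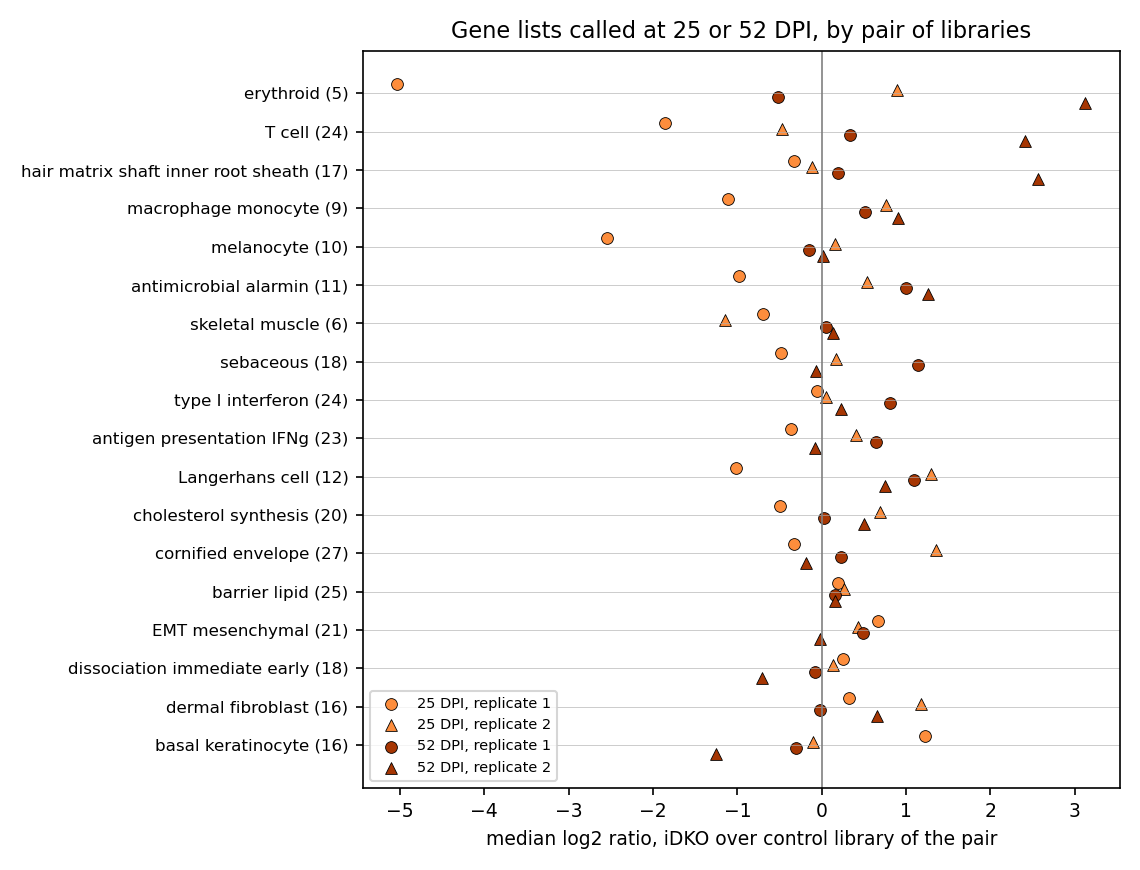
Median log2 ratio of the iDKO over the control library for each list called at 25 or 52 DPI, with the number of tested genes in brackets. Circles show the pair of replicate 1 libraries and triangles that of replicate 2, in orange for 25 DPI and brown for 52 DPI. The T cell list has medians of -1.86 and -0.47 at 25 DPI and 0.34 and 2.40 at 52 DPI, and the hair list stands high in 1 pair, with 2.56.

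With all libraries and no block the other 16 lists were called at neither time by camera with the preset correlation. Their median log2 fold changes at 25 and 52 DPI were 0.19 and 0.05 for spinous and granular keratinocytes (adjusted p = 0.253 and 0.529), 0.22 and 0.08 for epithelial junctions (0.235 and 0.31). For the actin cytoskeleton they were 0.10 and -0.06 (adjusted p = 0.521 and 0.795), and for the cell cycle 0.02 and -0.10 (0.964 and 0.326). For activated keratinocytes they were -0.28 and 0.18 (adjusted p = 0.454 and 0.361), for cytokines and chemokines 0.28 and 0.01 (0.253 and 0.309), and for the type 17 response -0.11 and 0.00 (0.964 and 0.3). Hair follicle stem and outer root sheath genes had medians of 0.05 and -0.16 (adjusted p = 0.604 and 0.21), endothelial genes -0.13 and 0.21 (0.604 and 0.468) and adipocyte genes 0.03 and 0.17 (0.833 and 0.31). The p53 and DNA damage genes had medians of -0.02 and -0.14 (adjusted p = 0.604 and 0.066), glycolysis and hypoxia genes -0.15 and 0.10 (0.532 and 0.48), and NRF2 and oxidative stress genes -0.27 and 0.06 (0.253 and 0.361). The circadian genes had medians of 0.12 and -0.26 (adjusted p = 0.521 and 0.3), the genes of the mitochondrial genome 0.35 and -0.06 (0.402 and 0.74), and the sex-linked genes 0.23 and 0 (0.52 and 0.815). The test pointed up at 25 DPI where the median was negative for activated keratinocytes and p53 genes, and down where it was positive for adipocyte genes. Some of these lists were called without 1 library, so their lack of a call is not stable. At 52 DPI cytokines were called as higher without control replicate 1 or iDKO replicate 2. Without control replicate 2 activated keratinocytes were called as higher and the cell cycle as lower. The mitochondrial list was called as lower without control replicate 1 or iDKO replicate 2, and as higher without control replicate 2.

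By camera with the preset correlation the genotype effect on T cell genes differed between the times, which also differed in sex. The difference of the log2 fold changes, 52 DPI minus 25 DPI, had a median of 2.85 over the list, with 24 of 24 members above 0 (camera, adjusted p = 1.08e-31, adjusted p = 0.47 with an estimated correlation). By the preset correlation this call stood without each of the 8 libraries in turn (highest adjusted p = 1.96e-07). Without control 25 DPI replicate 1 the median difference was 1.02 with 21 of 24 members above 0, and without the other libraries it was 2.34 to 3.68. Adjusted over the list alone edgeR called 0 of the 24 genes, and 15 with the replicate block within time. The hair shaft and inner root sheath list differed by a median of 2.90 (adjusted p = 2.2e-11 by camera, adjusted p = 0.47 with an estimated correlation), and had an adjusted p of 0.0692 without iDKO 52 DPI replicate 2. Of the 34 lists 9 differed by camera. Over single genes edgeR called 0 differences between the times, with 139 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. By edgeR with the replicate block within time 0 were called, with 1116 at an unadjusted p under 0.05. Across the 17839 genes the log2 fold changes at the 2 times correlated at -0.096 (Pearson) and -0.109 (Spearman). Without 1 library at a time the Pearson value lay between -0.111 and 0.077, above 0 without control 25 DPI replicate 1 (0.077) and without control 52 DPI replicate 2 (0.008). Genes are not independent replicates, so no p is given. Among genes at an unadjusted p under 0.05 by edgeR, 13 were higher at both times against 0.323 expected of independent lists, and 0 were lower at both. Both comparisons use the same estimate of each gene's spread, so the lists are not independent and 0.323 is not a chance level.

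Across both times Zeb1, Fkbp14, Flot2 and Ccdc88a were higher in the libraries labelled iDKO. This comparison sets 4 libraries labelled iDKO against 4 control libraries with time as a term and asks for the part of the genotype effect common to 25 and 52 DPI. Zeb1 (ENSMUSG00000024238, GRCm38 chromosome 18, 5591860 to 5775467, plus strand) was at 21.8 ± 9.36 against 2.62 ± 0.663 CPM (SD, n = 4 each), a log2 fold change of 3.08 (SE 0.38; DESeq2 adjusted p = 2.11e-10, edgeR adjusted p = 0.53). Fkbp14 had a log2 fold change of 3.40 (SE 0.53), Flot2, a membrane raft scaffold, 1.99 (SE 0.40), and Ccdc88a, an actin-binding regulator of cell migration, 1.53 (SE 0.29), each called by DESeq2 (adjusted p = 2.5e-07, 0.0109 and 0.00122). DESeq2 called 8 genes, all higher, among them also Zcchc24, Aox4 and Gm3650. With 1 of the 8 libraries left out at a time DESeq2 kept Zeb1 and Fkbp14 each time (highest adjusted p = 9.3e-06 and 0.0014). Its count lay between 3, without control or iDKO 25 DPI replicate 2, and 35, without control 25 DPI replicate 1. Flot2 was not called without control 25 DPI replicate 2, iDKO 25 DPI replicate 1 or 2, control 52 DPI replicate 2 or iDKO 52 DPI replicate 1 (adjusted p = 0.217, 0.1955, 0.256, 0.3255 and 0.718 by DESeq2). Ccdc88a was not called without the same 5 libraries (0.122, 0.1825, 0.1798, 0.1525 and 0.4615) or without control 52 DPI replicate 1 (0.0964). Their log2 fold changes by edgeR lay between 1.84 and 2.37 and between 1.38 and 1.63 without 1 library. Without each of the 4 pairs in turn DESeq2 with the replicate block within time called both (highest adjusted p = 8.52e-07 and 0.00257). Over all genes edgeR called 0, with 130 at an unadjusted p under 0.05, and limma-voom called 0. With the replicate block within time edgeR and limma-voom each called 1, and edgeR had 718 at an unadjusted p under 0.05. All 4 libraries labelled iDKO lay above all 4 control libraries for 84 genes and below them for 42, together 0.706% of the genes tested. Chance would give 2.86% if the 8 libraries were exchangeable, which the split by replicate number rules out, so the 2 shares are not comparable. In the simulation edgeR without a block recovered 1.49%, 25.4% and 77.3% of genes changed 2-, 4- and 16-fold in this comparison, and with the block within time 50.75%, 100% and 100%.

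Further genes had the same direction in all 4 pairs. Among the 10 higher genes with the smallest p under the replicate block within time, a selection made after the data were examined, Fez1, a neuronal transport adaptor, had a log2 fold change of 2.98 (SE 0.75), Lix1l 3.12 (SE 1.15), and Zcchc24 2.36 (SE 0.47). In the same set Cep170, a centrosomal protein, had 1.62 (SE 0.39), the kallikrein Klk10 1.32 (SE 0.31) and Dmwd 1.10 (SE 0.32). On the lower side the hair keratin Krt32 had -1.62 (SE 0.62, and -2.07 to -1.04 without 1 library), Sdcbp2, within 10 Mb of Ovol2, -1.06 (SE 0.32), Aknad1 -1.10 (SE 0.30), Fgd4, an exchange factor for Cdc42, -1.09 (SE 0.30), and Galnt3, a glycosyltransferase, -0.88 (SE 0.30). DESeq2 with the block called each of these 11 genes (highest adjusted p = 0.0148). They had been selected by p under the same block in the same libraries, so this is not independent support. EdgeR with that block, which ranked them, called none of them (adjusted p = 0.218 to 0.723). In simulated counts 36 of 225 calls of this DESeq2 fit were false. Of the 17839 genes 2396 went the same way in all 4 pairs, or 13.4% against 12.5% by chance. Across both times 9 of 34 lists were called by camera, 8 higher and 1, melanocytes, lower (median -0.70, adjusted p = 0.00751, adjusted p = 0.747 with an estimated correlation). The barrier lipid list rose with a median of 0.20 (adjusted p = 0.00065 by camera, adjusted p = 0.221 with an estimated correlation), and the mesenchymal list with 0.16 (0.00065 and 0.393 in the same order). The Langerhans cell list rose with a median of 0.60 and the fibroblast list with 0.71 (adjusted p = 0.00051 and 0.00106 by camera, adjusted p = 0.747 for both with an estimated correlation). The remaining 4 were antigen presentation (median 0.20, adjusted p = 0.0268 by camera), cholesterol synthesis (0.24, 0.0166), cornified envelope (0.41, 0.0268) and type I interferon (0.21, 0.0111), each with an adjusted p of 0.747 with an estimated correlation. The cornified envelope list was not called with the strand column (adjusted p = 0.0764) and the interferon list not without a filter (0.0804). Without control 25 DPI replicate 2 the adjusted p was 0.187 for the barrier lipid and 0.3705 for the Langerhans cell list. Without control 25 DPI replicate 1 it was 0.114 for the mesenchymal and 0.186 for the fibroblast list, and without iDKO 25 DPI replicate 2 it was 0.9885 for the fibroblast list. With the replicate block within time the epithelial junction list was called in addition, as higher (median 0.11, adjusted p = 0.0471 against 0.0758 without it), and not with an estimated correlation (adjusted p = 0.744 with the block and an estimated correlation).

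The time comparisons describe how the epidermis differed between 52 and 25 DPI within each genotype, with sex changing alongside. In control libraries DESeq2 called 14 genes, 2 higher and 12 lower at 52 DPI, and in libraries labelled iDKO 11, of which 6 were higher and 5 lower. Xist led the higher and the 4 Y-linked genes the lower calls in both. Among the others Tubb3, a neuronal tubulin, had a log2 fold change of -6.97 (SE 1.34, DESeq2 adjusted p = 0.000594) and Adh1, an alcohol dehydrogenase, of -4.94 (SE 1.11, DESeq2 adjusted p = 0.0146) in control. In libraries labelled iDKO the root sheath keratin Krt71 (8.30, SE 1.75, DESeq2 adjusted p = 0.00547) and Gjb2 (5.91, SE 1.32, DESeq2 adjusted p = 0.0151) were higher at 52 DPI, both from iDKO 52 DPI replicate 2. By edgeR 0 genes were called in either genotype, with 269 and 298 at an unadjusted p under 0.05, and limma-voom called 0.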

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

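The test of DESeq2 splits of the libraries and that of assignments within pairs were written down before their results were seen, and the other tests in this part were chosen only after the result was seen. The genotype effect differed between 25 and 52 DPI for 9 lists by camera on the difference itself. The median log2 difference, 52 minus 25 DPI, was 2.85 for T cells (adjusted p = 1.08e-31 by camera), 2.90 for hair shaft and inner root sheath (2.2e-11), and -0.89 for basal keratinocytes (5.86e-05). It was 1.65 for macrophages (6.26e-05), 7.24 for erythroid genes (1.98e-05), 1.18 for antimicrobial genes (0.00033), 1.80 for melanocytes (0.000925), 0.66 for type I interferon genes (0.0062) and 1.39 for skeletal muscle (0.0117). With an estimated correlation 0 of the 9 were called by camera, with unadjusted p between 0.0223 and 0.283. Without control 25 DPI replicate 1 the adjusted p was 0.644 for basal keratinocytes, 0.353 for antimicrobial genes, 0.5385 for melanocytes, 0.353 for macrophages and 0.825 for erythroid genes. The hair list had 0.0692 and the erythroid list 0.4998 without iDKO 52 DPI replicate 2, and the antimicrobial list 0.0737 without control 52 DPI replicate 1 and 0.0577 without a filter. For the interferon list it was 0.2426, 0.4345, 0.396 and 0.79 without control 25 DPI replicate 2, iDKO 25 DPI replicate 1, control 52 DPI replicate 2 and iDKO 52 DPI replicate 1. For skeletal muscle it was 0.437, 0.159, 0.115 and 0.068 without control 25 DPI replicate 2, iDKO 25 DPI replicate 1, control 52 DPI replicate 1 and iDKO 52 DPI replicate 1. Melanocytes had 0.0523 without iDKO 25 DPI replicate 1, and with the replicate block within time melanocytes had 0.0542 and erythroid genes 0.0674. Over single genes DESeq2 with the replicate block within time, chosen after the data were examined, called 39 differences, 2 of them (Cd3d and Cxcr6) in the T cell list.

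The T cell list was lower at 25 DPI and higher at 52 DPI in the libraries labelled iDKO. A lower share of keratinocytes would move other cell types alike, and in 2 of the 4 pairs the T cell median lay outside the range of the medians of melanocytes, Langerhans cells, fibroblasts and endothelium. The lower level at 25 DPI may come from a single library, since without control replicate 1 the list's median was 0.25, with 16 of 24 members higher and an adjusted p of 0.714. Whether a single library also carries the difference between the times is left open. Its median was 1.02 without that library, with a highest adjusted p of 1.96e-07 by camera over the 8 omissions, but with an estimated correlation the list was not called with all libraries (adjusted p = 0.47). Sex cannot be told apart from time, since each time held 1 kind of library by Y-linked transcripts. The erythroid list moved the same way as the T cell list, with medians of -4.96 at 25 and 2.27 at 52 DPI. It pointed up at 25 DPI without control replicate 1 and down at 52 DPI without iDKO replicate 2. Whether both lists moved for the same reason was not tested. A change in T cell number or state with the genotype stays open as a hypothesis and may depend on time or on sex.

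Zeb1 and 9 other genes were higher in the iDKO library of every pair. Since these genes were chosen for their rise, 10 were also chosen by the same rule from 3 pairs at a time and measured in the pair left out. Of these, 8 of 10 were higher in the pair of 25 DPI replicate 1 (lowest log2 ratio -2.04), and 10 of 10 in each other pair. The upper quartile of the fibroblast list lay below the lower quartile of the genes so chosen in 2 of the 4 pairs, and that of the T cell list in 3. In the pair of 52 DPI replicate 2 the upper quartiles of both lists, 2.29 and 2.54, lay above that lower quartile (1.202). In that of 25 DPI replicate 1 so did that of the fibroblast list (1.078 against 0.4667). The whole fibroblast list was higher in the pair of 25 DPI replicate 2 (lowest 0.288, median 1.18). Fibroblasts carried over from the dermis therefore stay open as a source. T cells are argued against at 25 DPI, where the median of their list was below 0 in both pairs (-1.86 and -0.47), and stay open at 52 DPI. The number of genes by edgeR across both times was 0, which 35 of the 35 splits of the 8 libraries reach of necessity, so this comparison decides nothing. The highest other had 5806, the split by replicate number, which points to that structure of the libraries. By DESeq2 the real split gave 8 genes and 11 of 35 splits gave as many (highest other 7725, by replicate number, with 86 for the split by time), so chance is not excluded for the count. Among the splits that part all 4 pairs the others gave at most 6. With the replicate block within time DESeq2 called 73 genes and 2 of 8 assignments gave as many (highest other 247), too few assignments for a share under 0.05, and without the pair of 25 DPI replicate 1 it called 274 and without that of replicate 2 20.

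The hair shaft and inner root sheath list was higher at 52 DPI, and a single library may carry it. Without iDKO 52 DPI replicate 2 its adjusted p was 0.913 by camera, and the median log2 ratio in the other pair was 0.20. Whether that mouse was in another phase of the hair cycle was not tested.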

How the results depend on the processing

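The fits with DESeq2 or limma-voom and a block, the block within time for lists, the omission of 2 libraries together, the strand column and DESeq2 without single libraries were chosen after seeing the data. Counts of genes by edgeR were 0 in all 6 comparisons with RLE, library size alone, a stricter filter, a log2 fold change of at least 1, without mitochondrial genes, the strand column, the replicate block and without any 1 library. At an unadjusted p under 0.05 edgeR without a block had 75 to 298, and limma-voom called 0. DESeq2 called 2 at 25 DPI, 1 at 52 DPI, 14 and 11 for time in control and iDKO, 8 across both times and 0 for the difference. Without a filter edgeR called 8, 25, 62, 37, 16 and 19 in the same order. DESeq2 with the replicate block called 9, 8, 40, 29 and 25, and 0 for the difference. DESeq2 with the block within time called 103 at 25 DPI, 35 at 52 DPI, 39 for the difference and 73 across both times, and across both times edgeR and limma-voom with that block called 1 each. The cause was not tested.

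Lists called numbered 9 at 25 DPI, 12 at 52 DPI, 9 for the difference and 9 across both times by camera, and 0 each with an estimated correlation, with fry, and with the block within time and an estimated correlation. Without 1 library they numbered 7 to 14, 9 to 12, 8 to 15 and 5 to 16 in the same order. The difference had 15 without iDKO 25 DPI replicate 2, and both times together had other counts without single libraries (16 without control 25 DPI replicate 1, 5 without control 25 DPI replicate 2, 14 without iDKO 52 DPI replicate 2). Without control 25 DPI replicate 1 and iDKO 52 DPI replicate 2 together there were 14 at 25 DPI. Across both times the adjusted p was at most 0.811 for antigen presentation, 0.989 for cholesterol synthesis and the cornified envelope, 0.416 for melanocytes and 0.651 for interferon genes without 1 library. Beyond the calls named in the report and above, the blocks added immediate-early genes for the difference (0.0315 and 0.0413) and changed no other list call.

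Of 83 named gene values 0 reversed under settings other than omitting a library, and 17 of 664 did so without 1 library. Uncalled by edgeR as designed, 10 of the 83 were called by edgeR without a filter and 7 by DESeq2. With the replicate block DESeq2 called 14 of them, and with the block within time 32. The log2 fold changes without 1 library spanned -0.0843 to 1.37 for Ovol2, -3.70 to 0.25 for Trac, -3.78 to 0.54 for Cxcr6, -3.27 to 0.46 for Dct, and -2.26 to 0.00567 for Pmel at 25 DPI. At this time they also spanned -1.94 to 5.31 for Col1a1, -0.63 to 3.33 for Col1a2, -2.91 to 0.20 for Hspa1a, -2.22 to 5.23 for Thbs1 and -0.0554 to 2.46 for Epgn. At 52 DPI they spanned -0.15 to 1.22 for Ovol1, -0.66 to 1.06 for Ovol2, -1.55 to 12.82 for Krt35, -3.53 to 7.17 for Krt25 and -0.51 to 5.399 for Gjb2.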

Other observations

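The test near the targeted genes was written down before its result was seen, and the test of the junction list and the gene calls in this part were chosen only after the data were examined. DESeq2 with the replicate block within time called 103 genes at 25 DPI and 35 at 52 DPI, and the genes named here were picked from them after their values were seen. Higher at 25 DPI were Nod2, a sensor of bacterial cell walls (log2 fold change 2.70, SE 0.40, adjusted p = 7.34e-08 by DESeq2), and Tnfaip3, an inhibitor of NF-kappaB (1.80, SE 0.40, 0.00326). Others were Nfkbiz, a nuclear regulator of the same factor (1.236, SE 0.26, 0.000847), and Icam1, an adhesion receptor for leukocytes (1.35, SE 0.33, 0.0132), and no list of such genes was tested. Without iDKO 25 DPI replicate 2 their log2 fold changes by edgeR were 0.14, 0.51, 0.44 and 0.31 in the same order. At 52 DPI Thbs1, a matrix glycoprotein (-1.61, SE 0.34, 0.0039), Epgn, a ligand of the EGF receptor (-1.29, SE 0.30, 0.0146), Ptgs2, a prostaglandin synthase (-1.83, SE 0.41, 0.00869), and Ch25h, a cholesterol hydroxylase (-2.43, SE 0.49, 0.00146), were lower by the same test. None of these was called by edgeR without a block (adjusted p = 1.00), and in simulated counts 36 of 225 calls of this DESeq2 fit across both times were false. At 25 DPI this fit called Thbs1 and Epgn as higher (1.455, SE 0.34, 0.00681, and 1.16, SE 0.30, 0.0261), and without iDKO 25 DPI replicate 2 their log2 fold changes by edgeR were -2.22 and -0.0554.

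DNA flanking the modified genes may add to the genes that moved the same way in all 4 pairs. Within 10 Mb of Ovol1 or Ovol2 17.9% of 352 genes did so, against 13.3% of 17474 elsewhere (odds ratio 1.42, p = 0.0175 by Fisher's exact test). Neighbouring genes are not independent, and the share with an unadjusted p under 0.05 across both times gave an odds ratio of 1.45 (p = 0.129 by the same exact test). Of the 73 genes called across both times by DESeq2 with the replicate block within time, 5 lay there (Sdcbp2, Sox12, Neat1, Gpha2 and Fads3).

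If a higher level of Zeb1 lowered epithelial junction transcripts, that list would be lower across both times. Its median log2 fold change was 0.11, and it was not called lower (camera, p = 0.379 with an estimated correlation). It was called as higher with the preset correlation under the replicate block within time (adjusted p = 0.0471) and with the strand column (0.0461), which goes against this explanation, though not with the block and an estimated correlation (adjusted p = 0.744). Its members went both ways (24 higher, 14 lower). The upper quartile of the list's log2 ratios was below 0 in the pair of 52 DPI replicate 1 (-0.0179). It was 0.925 and 0.382 in the pairs of 25 DPI replicates 1 and 2 and 0.655 in that of 52 DPI replicate 2. The pairs thus differ and the question stays open.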
